A study of Drosophila melanogaster with 36 samples.

How the data were processed

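Brains of wandering third-instar larvae were profiled by polyA-selected mRNA sequencing, in 6 genotypes, both sexes and 3 libraries per group, 36 libraries in all. Per the labels' protocols, larvae were raised at 25 °C, RNA was taken up in Trizol and cleaned with a Zymo kit, libraries were made with the KAPA stranded mRNA kit, and reads were paired-end of 100 bp. The deposited values are raw whole-number counts per gene, without normalization, 1 column per library. The submitters' processing notes name STAR 2.7.2a and Subread 2.0.3, without settings. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here. Of the values from 1 to 4, between 79.2% and 85.1% per library were even, as when both mates of a pair are counted separately, so values are called reads, not read pairs. Total reads counted in genes ran from 82.5 M to 143.8 M per library (median 103.0 M).

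Of 17606 genes in the table, 17527 were matched by identifier to Ensembl release 115, which gave the symbol and chromosome arm, and 79 were not matched (0.401% of reads). Antisense and overlapping genes, and near-identical copies, are uncertain, since the strand setting and the handling of shared reads are unknown. All computations used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The edgeR filter (filterByExpr over the 12 groups, minimum count 10) left 12167 genes, 2016 on the X, 9962 on arms 2L, 2R, 3L and 3R, 105 on chromosome 4 and 29 on the Y. TMM factors ran from 0.970 to 1.055. The quasi-likelihood model of edgeR was fitted once over 12 group means, with 24 residual degrees of freedom and a common biological coefficient of variation of 0.118. Adjusted p values are Benjamini-Hochberg values over the genes tested, called at 0.05, 2-sided. Levels are CPM with TMM factors. Where a group had 0 reads in all libraries, folds are bounds against a floor of 3 reads per library. Pairs of libraries within a group differed by a chi-square per degree of freedom of 8.19 to 96.1 where pure counting error gives 1, so the spread between libraries exceeds the counting error at this depth.

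Each mutant was compared with its control within each sex. Differences of the response between the sexes were tested as interactions in the same fit. Sex differences in controls were the mean of the male minus female contrasts of yw, H3.3WTH3.2HWT and H3.3CtrlH3.2HWT. The X-to-autosome shift was the median over X-linked genes minus the median over genes of arms 2L, 2R, 3L and 3R of log2 CPM (prior count 2), centred per gene on the 6 libraries compared. It was tested by exact 2-sided permutation of the 6 libraries, and differences of shifts by permuting labels within each pair (400 assignments). Chromosome 4 was measured in the same way after its calls had been seen. Overlaps of calls were compared with those of independent lists, n1 × n2 / N per direction.

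Gene lists, 39 in all, of which 32 were functional or marker lists and 7 chromosome arms, were tested with limma camera at a preset correlation of 0.01, adjusted over lists within a comparison. The test was repeated with an estimated correlation. Mitochondrial genome genes and replication-dependent histone genes had fewer than 3 tested genes and were left out, so 37 lists were tested. Of the list entries, 10 were matched by an alias and 3 were not found (Cdc20, esg and irbp18). The functional lists were antimicrobial and immune genes, cell cycle and DNA replication, cuticle and trachea, cytoplasmic and mitochondrial ribosomal proteins, detoxification, differentiated neurons, DNA damage and p53 response, dosage compensation, ecdysone response, eye disc, fat body, germline, glia, H3K36 methylation factors, heat shock, hemocyte, Hox and other Polycomb targets, imaginal disc, muscle, neural stem cells, neuropeptides, odorant binding and gustatory proteins, oxidative phosphorylation, Polycomb and trithorax group, proteasome, ring gland, salivary gland, sex determination, and testis and sperm. With an estimated correlation, 8 of the 82 list calls kept adjusted p under 0.05.

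Named genes followed a rule. It took Set2, both H3.3 genes, roX1, roX2, msl-2 and Sxl throughout. Per mutant and sex it took the 6 largest rises and falls among called genes at 5 CPM or more whose libraries did not overlap between the groups, without bare annotation numbers. It took up to 4 members of each functional list that passed, by smallest p. It took up to 5 genes with the smallest p per interaction, the 5 largest rises and falls between control sexes, and the 4 smallest worst p for genes called in both sexes of a mutant or in all 3 mutants. The design, lists, naming rule and most alternatives were chosen before the data were examined.

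Whether the replicate numbers pair libraries was checked from the correlation of deviations from group means. Same-numbered libraries correlated above 0.1 in every pair for H3.2K36R female mutants and controls (r between 0.105 and 0.340), for males and females of H3.3WTH3.2HWT (between 0.137 and 0.281) and of H3.3WTH3.2K36R (between 0.245 and 0.679). The labels name no shared day or batch.

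The pipeline was tested on simulated data. In simulated Set2 males, edgeR recovered 80.6% of genes planted at a log2 change of 0.5, 98.5% at 1 and 100% at 2, with 12 false calls (6.06% of calls), against 85.1%, 100% and 100% and 17 false calls (8.21%) with DESeq2. An X shift of -0.15 planted in simulated H3.3K36R females was recovered as -0.145, with camera adjusted p = 3.8e-51 for the X list, and 1 of the other lists was called.

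Alternatives were DESeq2, RLE size factors, TMM factors from autosomal genes, other low-count filters, a fold threshold, only the compared libraries, a replicate block, other prior counts and means, an estimated correlation and fry for lists, and leaving out each library. Alternatives added after seeing the data were a roX2 covariate in female libraries, a replicate block across sexes, permuted sex labels, halved counts, and both H3.2 genotypes reduced to libraries 2 and 3. No library was left out of the main results. Total RNA sequencing of younger larvae named in the series design was not analysed here. The first code for the roX2 test in female libraries also asked for a permutation p under 0.05 without the 2 farthest libraries. After the values were seen, this was relaxed to the prediction as first written, which the values without those libraries would not have met. A correlation of roX2 with Y-linked RNA, as a share of the males of the same genotype, was run in the first code, removed after its values were seen and later put back. It was also run without yw, whose males hold almost no Y-linked RNA.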

Results

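The data were messenger RNA profiles of brains from wandering third-instar larvae of Drosophila melanogaster, in 6 genotypes and both sexes. Each of the 12 groups held 3 libraries, 36 in all, with between 82.5 and 143.8 M reads counted in genes (median 103.0 M) and 12726 to 14349 genes with a read. Set2 encodes the enzyme that trimethylates lysine 36 of histone H3. H3.2 is the histone made during DNA replication and H3.3 the variant made throughout the cell cycle. Mutants whose names end in K36R carry arginine in place of that lysine. The H3.2 mutant (H3.3WTH3.2K36R) was compared with H3.3WTH3.2HWT. The H3.3 mutant (H3.3K36RH3.2HWT) was compared with H3.3CtrlH3.2HWT, and the Set2 mutant (Set21) with yw, each within a sex. These pairs share no libraries. The labels do not say whether the libraries of a group come from separate animals or pools. Levels are read counts scaled to library size with TMM factors (CPM), given as mean ± SD over n = 3 libraries unless stated, and fold changes are log2 values from 1 edgeR fit over 12167 genes. The genome build is not given in the sources used here, so genes carry only their chromosome arm.

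Set2 (FBgn0030486, arm X) stood at 28.9 ± 0.904 CPM in Set21 males against 198 ± 2.84 in yw males, and at 32.1 ± 1.08 in Set21 females against 185 ± 4.17 in yw females. It fell by 2.78 on the log2 scale in males (adjusted p = 7.6e-30) and by 2.52 in females (adjusted p = 7.7e-29). In the other 8 groups Set2 ranged from 164 ± 4.03 to 189 ± 3.11 CPM. His3.3A, 1 of the H3.3 genes, was low in both H3.3 genotypes, the control included (from 65.6 ± 4.87 to 69.4 ± 4.31 CPM over 4 groups). In the remaining 8 groups His3.3A ranged from 249 ± 9.17 to 353 ± 33.9 CPM. The substitutions themselves cannot be read from counts per gene.

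Control brains differed between the sexes mainly on the X chromosome. The noncoding RNAs roX1 and roX2, parts of the complex that raises X expression in males, were higher in the 9 male than in the 9 female control libraries: roX2 (FBgn0019660, arm X) at 54.1 ± 13.5 CPM against 5.18 ± 4.99 (n = 9, log2 fold change 3.78, adjusted p = 5.7e-08) and roX1 with a log2 fold change of 2.41 (adjusted p = 1.4e-10). The mRNA of msl-2, the male-limiting protein of that complex, was also higher in males (132 ± 10.8 CPM against 63.7 ± 9.02, log2 fold change 1.06, adjusted p = 6.8e-15). Sxl, the female-determining splicing regulator, was lower in males (303 ± 32.3 CPM against 666 ± 86.7, log2 fold change -1.13, adjusted p = 2.4e-14). Among the 11 dosage compensation genes 7 rose and 1 fell in males (7 and 1 adjusted over the list), with adjusted p = 2.4e-08, and 0.0016 with estimated correlation.

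Further named genes were ssx (log2 fold change 0.46) and nod (0.44) higher in males, and lawc (-0.53), yin (-0.51), Ldaf1 (-0.41) and HLH3B (-0.39) lower, all X-linked. His3.3B, also X-linked, was lower in males (log2 fold change -0.16, adjusted p = 6.5e-06), and Set2 higher by 0.070 (adjusted p = 0.017). In all, 990 genes differed, 383 higher and 607 lower in males. Of 2016 X-linked genes, 185 were higher and 499 were lower in males (239 and 631 adjusted over the list). Their adjusted p was 2.1e-08, and 8.7e-05 with estimated correlation. X-linked genes were over-represented among the lower genes, against genes of arms 2L, 2R, 3L and 3R (odds ratio 31.2, Fisher's exact test across genes, p = 5.3e-299). They were also over-represented among the higher genes (odds ratio 5.49, Fisher's exact p = 8.6e-52). Of 105 chromosome 4 genes, 10 were higher and 2 were lower in males (10 and 2 adjusted over the list). As a list they had adjusted p = 0.0032, and 0.79 with estimated correlation. Of 29 Y-linked genes, 6 were higher and 0 were lower in males (10 and 0 adjusted over the list). Camera gave them adjusted p = 1.9e-13, and 0.073 with estimated correlation. Of 30 neuropeptide and insulin-like peptide genes, 0 were higher and 3 were lower in males (0 and 5 adjusted over the list). Tested together, they had adjusted p = 0.0024, and 0.67 with estimated correlation. Of 25 genes of differentiated neurons, 0 were higher and 2 were lower in males (0 and 2 adjusted over the list). For this list adjusted p was 0.0062, and 0.73 with estimated correlation. Of 72 mitochondrial ribosomal proteins, 1 were higher and 5 were lower in males (1 and 6 adjusted over the list). Against all other genes, adjusted p was 0.0062, and 0.79 with estimated correlation. Of 10 salivary gland genes, 2 were higher and 0 were lower in males (5 and 0 adjusted over the list). This set had adjusted p = 0.012, and 0.79 with estimated correlation.

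Some female libraries held roX2, a male transcript. Its level ran from 0.0930% of the mean of the males of the same genotype (a yw female library) to 35.7% (an H3.3WTH3.2HWT female library), and all 3 female libraries of H3.3WTH3.2HWT were at 17.4% or above. The Y-linked gene FDY was close to absent in yw males (0.205 ± 0.162 CPM), against 4.91 ± 1.29 in Set21 males, 15.7 ± 1.35 in H3.3WTH3.2HWT males and 44.6 ± 2.77 in H3.3WTH3.2K36R males. In the H3.3WTH3.2HWT and H3.3WTH3.2K36R female libraries with the most roX2 of their genotype (15.5 and 7.99 CPM), FDY reached 13.3 and 12.8 CPM.

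**Figure D1:**
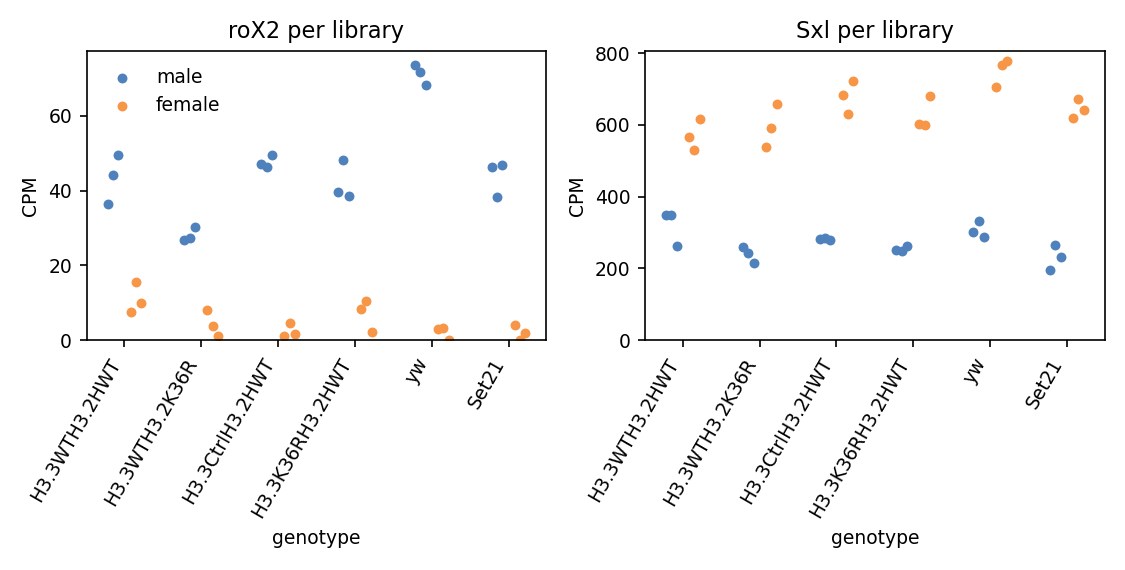
Levels of roX2 and Sxl (CPM) in each of the 36 libraries by genotype, males and females in different colours, 3 points per group. Male control libraries held 54.1 CPM of roX2 on average against 5.18 in female ones, with an H3.3WTH3.2HWT library the highest among females.

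Brains of the H3.2K36R mutant gained transcripts of germline genes in both sexes. Several neural stem cell genes fell, but as a list only with the preset correlation (adjusted p = 0.17 in males and 0.15 in females with an estimated one). Marf1 (FBgn0039972, arm 2L), an RNA-binding regulator of oocyte meiosis, stood at 119 ± 5.97 CPM against 5.65 ± 0.790, log2 fold change 4.40, adjusted p = 8.7e-15 in males, and at 123 ± 2.61 CPM against 8.17 ± 0.141 in females (log2 fold change 3.91, adjusted p = 6.9e-14). The piRNA pathway genes qin (males 19.4 ± 0.232 CPM against 2.87 ± 0.170, log2 fold change 2.76, adjusted p = 5.4e-16) and krimp (38.7 ± 1.43 CPM against 9.90 ± 0.604, log2 fold change 1.97, adjusted p = 5.2e-15) rose, as did blanks, which encodes an RNA-binding protein of the testis (39.9 ± 1.31 CPM against 1.57 ± 0.471, log2 fold change 4.69, adjusted p = 5.2e-15). In females the log2 fold changes were 2.55 for qin, 1.92 for krimp and 5.0 for blanks. The neural stem cell noncoding RNA cherub (FBgn0262972, arm 3R) fell from 10186 ± 1743 to 2096 ± 41.4 CPM in males (log2 fold change -2.28, adjusted p = 9.1e-14) and by 2.55 on the log2 scale in females. The temporal factor cas of neural stem cells fell as well (28.6 ± 1.14 CPM against 106 ± 18, log2 fold change -1.89, adjusted p = 1.5e-12 in males, and log2 fold change -1.87 in females).

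The largest male rises were ord, a factor of sister chromatid cohesion in meiosis (15.7 ± 0.644 CPM against 0.00468 ± 0.00810), HP6 (8.72 ± 0.710 CPM against 0.0347 ± 0.0247), RpL37-2 (8.33 ± 0.580 CPM against 0.0609 ± 0.0531), gNacalpha (23.5 ± 1.17 CPM against 0.189 ± 0.135), the germline gap junction gene zpg (5.91 ± 0.139 CPM against 0.0836 ± 0.0585) and RpL22-like (28.4 ± 1.99 CPM against 0.174 ± 0.119), whose reads may be shared with its paralog RpL22. In females RpL37-2 stood at 5.36 ± 0.588 CPM against 0 reads in all 3 controls, at least 180-fold higher against a floor of 3 reads per library. Such intervals and floors cover counting error only. The female list also held ord, HP6, gNacalpha, RpL22-like and eIF4E3 (log2 fold change 6.64). Dhc98D, a dynein heavy chain, and Rcd-1r rose in both sexes (log2 fold changes 4.43 and 5.34 in males, 4.51 and 4.69 in females). Besides cherub and cas, the largest falls in both sexes included Pex7, a peroxisomal import receptor (-1.75 in males, -2.63 in females), Sol1 (-1.65 and -1.79) and PPO2, a hemocyte prophenoloxidase (-1.74 and -1.76). In males nyo fell (log2 fold change -1.92, adjusted p = 0.0084), a call lost when only the 6 compared libraries were fitted (adjusted p = 0.066), with the replicate block (adjusted p = 0.053) and without control male library 1 (adjusted p = 0.19). In females Hsp70Bb, a heat shock gene with near-identical copies, had a log2 fold change of -1.62 (adjusted p = 0.018), and its level cannot be assigned to 1 copy. That call is lost without control female library 3 (adjusted p = 0.085) or mutant female library 3 (adjusted p = 0.10).

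Of 26 germline genes, 17 rose and 1 fell in males and 15 and 1 in females (17 and 2, and 15 and 3, adjusted over the list). Camera on this list gave adjusted p = 9.1e-12 in males and 3.2e-09 in females, and 2.4e-05 and 1.5e-04 with estimated correlation. An example is nanos, a translational repressor of germ cells (13.2 ± 1.11 CPM against 0.189 ± 0.0426, log2 fold change 6.14, adjusted p = 1.0e-13 in males, log2 fold change 5.11 in females). Of 17 testis and sperm genes, 5 rose and 1 fell in males and 4 and 2 in females (5 and 2, and 4 and 2, adjusted over the list). Taken as a set, they had adjusted p = 0.20 in males and 0.13 in females, and 0.61 and 0.53 with estimated correlation. That list did not pass. Of 18 neural stem cell genes, 1 rose and 11 fell in males and 0 and 13 in females (1 and 11, and 1 and 14, adjusted over the list). Relative to other genes they had adjusted p = 1.7e-07 in males and 7.6e-08 in females, and 0.17 and 0.15 with estimated correlation. Members were the transcription factors grh (log2 fold change -0.97 in males, -0.81 in females), sc (-1.98 and -1.53) and svp (-0.24 in males). The adaptor of asymmetric division mira fell in females (-0.45).

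Of 29 cell cycle and DNA replication genes, 0 rose and 11 fell in males and 0 and 22 in females (0 and 11, and 0 and 23, adjusted over the list). With the preset correlation adjusted p was 3.6e-05 in males and 7.2e-09 in females, and 0.67 and 0.53 with estimated correlation. The kinases aurB (log2 fold change -0.43 in males, -0.46 in females) and Cdk1 (-0.33 and -0.34) and the helicase factor Cdc45 (-0.32 and -0.32) were among them. Of 24 Polycomb and trithorax group genes, 0 rose and 13 fell in males and 0 and 11 in females (0 and 14, and 0 and 11, adjusted over the list). Jointly they had adjusted p = 3.0e-06 in males and 1.1e-05 in females, and 0.21 and 0.33 with estimated correlation. Examples are Psc (log2 fold change -0.34 in males and -0.26 in females), brm (-0.23 and -0.21) and pho (-0.31 and -0.22). Of 29 Hox and other Polycomb target genes, 1 rose and 11 fell in males and 1 and 10 in females (1 and 14, and 2 and 12, adjusted over the list). The set test gave adjusted p = 6.8e-04 in males and 0.010 in females, and 0.21 and 0.44 with estimated correlation. Among them were toy (-0.45 and -0.37) and, in males, ey (-0.43), both eye selector genes. Of 14 writers, erasers and readers of H3K36 methylation, 0 rose and 5 fell in males and 0 and 6 in females (0 and 6, and 0 and 7, adjusted over the list). Their adjusted p was 0.014 in males and 0.0031 in females, and 0.46 and 0.43 with estimated correlation. The demethylase gene Kdm2 changed by -0.20 in males and -0.14 in females, the methyltransferase gene ash1 by -0.20 in males, and MRG15 by -0.21 in females.

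Of 21 DNA damage and p53 response genes, 9 rose and 2 fell in males (10 and 2 adjusted over the list). As a list they had adjusted p = 0.038, and 0.32 with estimated correlation. Among its members Corp (log2 fold change 1.21), Gadd45 (0.77) and p53 (0.67) rose. Of 72 mitochondrial ribosomal proteins, 0 rose and 14 fell in females (0 and 11 adjusted over the list). Camera gave them adjusted p = 0.0053, and 0.66 with estimated correlation. Among them mRpL18 (-0.31) and mRpL2 (-0.18) fell. Of 32 proteasome genes, 0 rose and 9 fell in females (0 and 10 adjusted over the list). Tested together, they had adjusted p = 0.029, and 0.74 with estimated correlation. Rpn12 (-0.14), Rpn5 (-0.12) and Prosbeta6 (-0.13) fell. Of 73 oxidative phosphorylation genes, 2 rose and 21 fell in females (2 and 24 adjusted over the list). For this list adjusted p was 0.0027, and 0.66 with estimated correlation. That list had a median log2 fold change of -0.10 and a mean of 0.071, which differ in sign. ATPsynbeta (-0.19) and ATPsynD (-0.16) fell. The paralogs ATPsynepsilonL (2.87) and ATPsynGL rose, the second at least 20.1-fold against the floor of 3 reads per library, with 0 reads in all 3 controls.

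Markers of other tissues moved with the H3.2K36R groups. Of 12 eye disc genes, 0 rose and 4 fell in males and 0 and 7 in females (0 and 8, and 0 and 7, adjusted over the list). Against all other genes, adjusted p was 0.0081 in males and 0.0013 in females, and 0.32 and 0.33 with estimated correlation. Among them was ato (log2 fold change -0.66 in males and -0.84 in females). Of 17 imaginal disc genes, 1 rose and 6 fell in males (2 and 8 adjusted over the list). This set had adjusted p = 0.014, and 0.21 with estimated correlation. They include vg (-0.64), salm (-0.40) and wg (-1.19). Of 13 hemocyte genes, 0 rose and 4 fell in males and 0 and 4 in females (0 and 4, and 0 and 4, adjusted over the list). Camera on this list gave adjusted p = 0.032 in males and 0.024 in females, and 0.61 and 0.56 with estimated correlation. The collagen gene vkg was at -1.48 in males and -1.49 in females and PPO1 at -5.67 and -5.73. Of 11 ring gland genes, 0 rose and 3 fell in females (0 and 3 adjusted over the list). Taken as a set, they had adjusted p = 0.022, and 0.66 with estimated correlation. Of these nvd was at -1.60 and spok at -1.24, and the call of spok is lost without H3.3WTH3.2K36R female library 3 (adjusted p = 0.094). Other members of the lists that passed lose their call in at least 1 setting (highest adjusted p): in males Jasper (0.10), lz (0.30), ro (0.23), Col4a1 (0.089) and al (0.32), and in females yem (0.056), Col4a1 (0.074), mRpL30 (0.053), mRpL3 (0.092), Prosalpha4 (0.054) and Akh (0.082).

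Of 105 chromosome 4 genes, 12 rose and 30 fell in H3.2K36R males (12 and 31 adjusted over the list). Relative to other genes they had adjusted p = 0.0081, and 0.67 with estimated correlation. Of 29 Y-linked genes, 17 rose and 0 fell in H3.2K36R males (19 and 0 adjusted over the list). With the preset correlation adjusted p was 1.1e-09, and 0.21 with estimated correlation. Sxl fell in males (log2 fold change -0.43, adjusted p = 0.0017). In females His3.3A (-0.29, adjusted p = 4.3e-04) and msl-2 (-0.28, adjusted p = 0.016) fell. The call of msl-2 is lost without control female library 2 (adjusted p = 0.16), without mutant female library 3 (adjusted p = 0.15) and when only the compared libraries are fitted (adjusted p = 0.11). The level of msl-2 moved with the male transcript roX2 (4.28 ± 3.48 CPM against 11 ± 4.08), and in both groups the library with the most roX2 had the most msl-2 (68.7 and 82.7 CPM).

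In H3.2K36R males 3091 of 12167 genes passed an adjusted p of 0.05, 1493 higher and 1598 lower, and in females 3018, 1351 higher and 1667 lower. Of these, 728 and 620 changed at least 2-fold. The test was the quasi-likelihood test of edgeR with 3 libraries per group. X-linked genes were over-represented among the lower (odds ratio 1.67, Fisher's exact test across genes, p = 3.4e-14) and the higher genes (odds ratio 1.64, p = 1.3e-12) in males. In females the odds ratios were 1.12 (Fisher's exact p = 0.11) and 1.53 (p = 7.4e-09). Library 1 of the mutant stood apart from libraries 2 and 3 in both sexes on principal component 4 (19.9 or higher against -20.6 or lower). With only libraries 2 and 3 of both H3.2 genotypes, 2187 genes passed in males and 2225 in females.

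**Figure D2:**
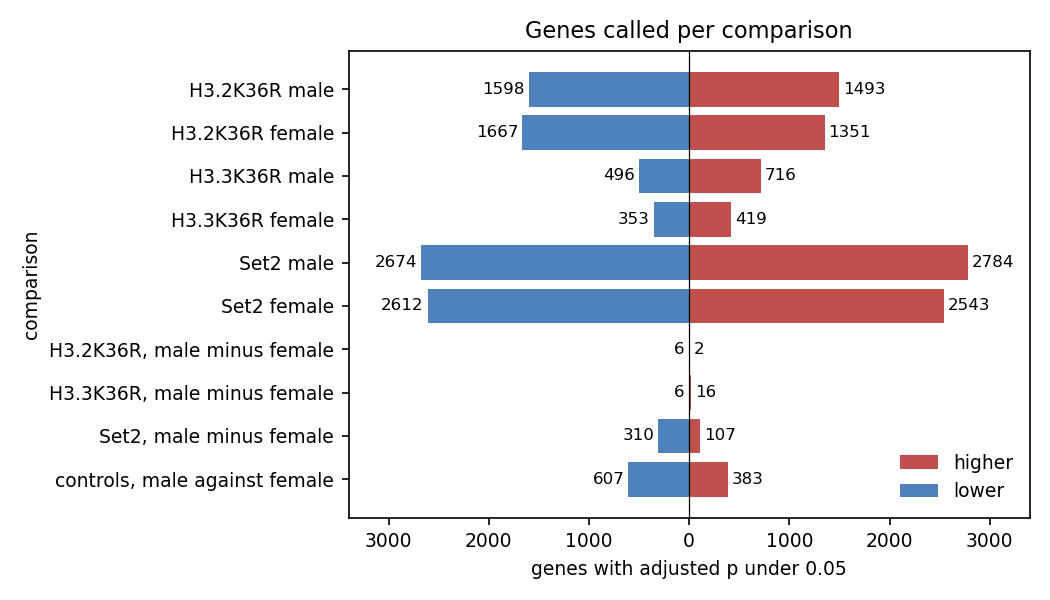
Number of genes with an adjusted p under 0.05 in each comparison (bars, higher to the right and lower to the left of 0). Set2 mutants had 5458 called genes in males and 5155 in females, against 772 to 3091 in the histone mutants.

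The H3.3K36R mutant changed fewer genes than the other mutants, and mfr, TrpA1, ppk20 and ppk30, among its largest falls, were high in its own control genotype alone. GILT3, a thiol reductase gene (FBgn0039098, arm 3R), rose from 1.12 ± 0.0827 to 15.2 ± 0.785 CPM in males (log2 fold change 3.76, adjusted p = 3.3e-18) and by 4.02 in females. Rubicon, an autophagy regulator on the X (64.0 ± 1.11 CPM against 20.9 ± 1.45, log2 fold change 1.62, adjusted p = 1.7e-17 in males, log2 fold change 1.15 in females), and Mgstl, a glutathione transferase gene on the X (31.7 ± 0.906 CPM against 117 ± 6.36, log2 fold change -1.88, adjusted p = 8.6e-22 in males, log2 fold change -1.36 in females), moved in opposite directions. The sperm gene mfr (FBgn0266757, arm 3L) stood at 0.0393 ± 0.0359 CPM against 52.8 ± 5.10 in males and 0.0194 ± 0.00112 CPM against 33.7 ± 19.5 in females. In the other 10 groups mfr lay between 0.0141 and 0.0517 CPM. The sensory channel gene TrpA1 (5.35 ± 0.399 CPM against 29.8 ± 1.25 in males) likewise lay between 3.53 and 5.65 CPM in those groups, which were looked at after the values were seen.

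The channel genes ppk20 (log2 fold change -8.0 in males, -8.19 in females) and ppk30 (-6.70 and -6.18) also fell, from 10.8 ± 3.88 and 8.29 ± 2.63 CPM in control males. They lay at most at 0.0820 and 0.145 CPM outside that genotype, with the limit that members of this family share sequence. The receptor gene mthl8 had 0 reads in all control libraries and 17.8 ± 4.32 CPM in mutant males and 17.1 ± 1.05 in mutant females, at least 546-fold and 654-fold higher against the floor of 3 reads per library. Further rises in both sexes were Ugt302K1, a glycosyltransferase gene (3.62 and 3.69), Cyp6t1, a cytochrome P450 gene (2.72 and 2.29), pst, an antiviral gene (2.30 and 2.62), and Marf1 (2.38 and 1.51). In females krimp rose by 1.52 (adjusted p = 2.3e-12), and Cyp4g1 fell by 2.03 on the log2 scale (adjusted p = 0.047). The call of Cyp4g1 is lost without control female library 1, 2 or 3 (adjusted p = 0.067, 0.084 and 0.11), without mutant female library 1 or 3 (adjusted p = 0.18 and 0.22) and when only the compared libraries are fitted (adjusted p = 0.18).

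Of 25 genes of differentiated neurons, 6 rose and 2 fell in H3.3K36R males (9 and 2 adjusted over the list). Jointly they had adjusted p = 0.043, and 0.78 with estimated correlation. The synaptic genes Snap25 (0.26) and nSyb (0.24) rose, and the sodium channel gene para (-0.63) and Ddc (-0.52) fell. Of 32 proteasome genes, 0 rose and 7 fell in males (0 and 12 adjusted over the list). The set test gave adjusted p = 3.7e-08, and 0.78 with estimated correlation. Prosalpha4 was at -0.36, while Rpn7, Prosbeta7 and Prosalpha5 lose their calls without mutant male library 1 (adjusted p = 0.083, 0.089 and 0.092) and in other settings. Of 72 mitochondrial ribosomal proteins, 5 rose and 0 fell in males (3 and 0 adjusted over the list). Their adjusted p was 0.0030, and 0.78 with estimated correlation. Of these, mRpS10, mRpL35 and mRpL15 lose their calls without control male library 2 (adjusted p = 0.090, 0.075 and 0.098) and mRpS26 without control male library 1 (0.076), among other settings. Of 12 eye disc genes, markers of another tissue, 0 rose and 4 fell in males (0 and 5 adjusted over the list). As a list they had adjusted p = 6.6e-05, and 0.45 with estimated correlation. They included eya (-0.46) and so (-0.49), while lz and gl lose their calls without control male library 3 (adjusted p = 0.18 and 0.13), with the replicate block (0.096 and 0.058) and without mutant male library 2 (0.16 and 0.063) or 3 (0.073 and 0.092). The next list also holds eya. Of 29 Hox and other Polycomb targets, 0 rose and 2 fell in males (0 and 2 adjusted over the list). Camera gave them adjusted p = 0.046, and 0.78 with estimated correlation. The other called one, ph-p, loses its call without control male library 1 or 3 (adjusted p = 0.079 and 0.078) or mutant male library 2 or 3 (0.10 and 0.081). Of 29 Y-linked genes, 3 rose and 0 fell in males and 7 and 0 in females (3 and 0, and 9 and 0, adjusted over the list). Tested together, they had adjusted p = 6.1e-05 in males and 3.1e-06 in females, and 0.78 and 0.77 with estimated correlation. In these females the male transcript roX2 (6.97 ± 4.40 CPM against 2.48 ± 1.98) and FDY (4.47 ± 2.01 CPM against 0.672 ± 0.287) moved with that list.

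Of 29 cell cycle genes, 0 rose and 1 fell in males and 0 and 1 in females (0 and 1, and 0 and 1, adjusted over the list). For this list adjusted p was 0.026 in males and 7.1e-05 in females, and 0.78 and 0.97 with estimated correlation. The called one was stg in each sex (log2 fold change -0.24 and -0.21). In females the call of stg is lost without control female library 1 or 3 (adjusted p = 0.062 and 0.11) or mutant female library 2 (adjusted p = 0.17), or when only the compared libraries are fitted (adjusted p = 0.19). The heat shock list passed in males with 0 of 15 members called by edgeR in either direction (adjusted p = 0.046, and 0.78 with estimated correlation). The ring gland list passed in females with 0 of 11 called (adjusted p = 0.0045, and 0.97 with estimated correlation). Of 10 salivary gland genes, markers of another tissue, 0 rose and 4 fell in males (0 and 7 adjusted over the list). Against all other genes, adjusted p was 0.0022, and 0.78 with estimated correlation. Of these Sgs3 stood at 0.288 ± 0.0969 CPM against 5.68 ± 7.36, with a spread above its mean in the controls. The calls of Sgs3, Sgs8 and Eig71Ee are lost without control male library 2 (adjusted p = 0.30, 0.30 and 0.35). They are also lost without mutant male library 1 (adjusted p = 0.070, 0.12 and 0.11), 2 (0.096, 0.10 and 0.13) or 3 (0.087, 0.12 and 0.092), and those of Sgs3 and Eig71Ee with the replicate block (0.086 and 0.12).

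In H3.3K36R males 1212 genes passed, 716 higher and 496 lower, 264 of them at least 2-fold, and in females 772, 419 higher and 353 lower, 228 of them at least 2-fold. X-linked genes were over-represented among the lower genes (odds ratio 3.37 in males, Fisher's exact test across genes, p = 8.9e-33, and 3.73 in females, p = 8.5e-29) and the higher ones (odds ratio 1.94 in both, p = 9.3e-13 and 2.9e-08). The male count is 746 without mutant male library 2 and 792 without control male library 2. The female count is 320 when only the 6 compared libraries are fitted.

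Loss of Set2 changed more genes than either histone mutant, in both directions. The photolyase gene phr (FBgn0003082, arm 2R) fell from 56.4 ± 1.5 to 13.8 ± 1.36 CPM in males (log2 fold change -2.04, adjusted p = 1.5e-22) and by 1.91 on the log2 scale in females. The protease gene gd on the X fell (1.98 ± 0.302 CPM against 9.30 ± 0.311, log2 fold change -2.23, adjusted p = 1.1e-15 in males, log2 fold change -4.04 in females), as did Cyp4g1, a cytochrome P450 gene on the X (-3.81 and -4.88). IFT57, a gene of cilium transport (16.2 ± 0.841 CPM against 0.262 ± 0.0718, log2 fold change 5.94, adjusted p = 1.8e-17 in males, log2 fold change 5.32 in females), and Tektin-C, a gene of sperm tails (21.3 ± 1.65 CPM against 0.499 ± 0.0828, log2 fold change 5.42, adjusted p = 7.7e-17 in males, log2 fold change 6.33 in females), rose. Further rises in both sexes were Ugt302K1 (4.80 and 4.62), GILT3 (3.75 and 3.96) and Marf1 (3.02 and 3.78). Ir40a rose in males (4.27), and Cyp12a4 fell in females (-2.63).

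Some of the largest differences set yw apart from the 10 other groups. Cyp4p2 was at 57.2 ± 0.768 CPM in yw males and 64.4 ± 5.60 in yw females and at most 0.0952 in any other group (log2 fold change -10.26 in males, -10.09 in females). Cyp4p1 was at 15.8 ± 0.890 and 20.5 ± 1.46 CPM against at most 0.104 elsewhere. Reads cannot be assigned with certainty between Cyp4p1 and Cyp4p2. The coat protein gene Sec31 was at 304 ± 4.08 CPM in yw males and between 148 and 157 outside yw (log2 fold change -1.0 and -1.02). The chemoreceptor gene Ir76a was at 0.383 ± 0.0519 CPM in yw males and at least 8.03 outside yw (log2 fold change 4.51 and 4.46). These other groups were looked at after the values were seen.

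Many cytoplasmic ribosomal protein and nerve cell genes fell in Set2 mutants, but the lists did not pass with estimated correlation. Of 90 cytoplasmic ribosomal proteins, 7 rose and 41 fell in males and 3 and 50 in females (7 and 42, and 5 and 54, adjusted over the list). This set had adjusted p = 6.0e-05 in males and 3.5e-07 in females, and 0.77 and 0.69 with estimated correlation. RpL18 was at -0.43 in males and -0.50 in females and RpS12 at -0.40 and -0.38. Of 25 genes of differentiated neurons, 1 rose and 15 fell in males and 0 and 12 in females (1 and 16, and 0 and 12, adjusted over the list). Camera on this list gave adjusted p = 2.0e-04 in males and 2.7e-04 in females, and 0.34 and 0.45 with estimated correlation. The acetylcholine synthesis gene ChAT stood at 48.2 ± 6.44 CPM against 69.4 ± 2.50 in males (log2 fold change -0.53, and -0.57 in females). The transporter gene VAChT (-0.43 and -0.39) and the synaptic gene Syx1A (-0.26 and -0.29) fell too. Of 30 neuropeptide and insulin-like peptide genes, 1 rose and 13 fell in males and 0 and 14 in females (1 and 13, and 0 and 14, adjusted over the list). Taken as a set, they had adjusted p = 0.016 in males and 0.012 in females, and 0.56 and 0.63 with estimated correlation. The diuretic hormone gene Dh31 stood at 21.1 ± 2.60 CPM against 30.9 ± 1.97 in males (log2 fold change -0.55, and -0.54 in females). The peptide genes sNPF (-0.43 and -0.53) and Mip (-0.47 and -0.43) also fell in both sexes.

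Of 18 neural stem cell genes, 0 rose and 12 fell in males and 0 and 13 in females (0 and 12, and 0 and 15, adjusted over the list). Relative to other genes they had adjusted p = 0.0057 in males and 3.8e-04 in females, and 0.41 and 0.45 with estimated correlation. Among them klu was at -0.34 and -0.34 and svp at -0.23 and -0.19. Of 29 Hox and other Polycomb targets, 0 rose and 13 fell in males and 0 and 14 in females (0 and 13, and 0 and 14, adjusted over the list). With the preset correlation adjusted p was 0.0096 in males and 0.021 in females, and 0.34 and 0.45 with estimated correlation. In this list eya was at -0.48 and -0.44. Of 24 Polycomb and trithorax group genes, 1 rose and 14 fell in females (1 and 14 adjusted over the list). Jointly they had adjusted p = 0.0016, and 0.45 with estimated correlation. They include pho (-0.32), and ph-p and ph-d, near-identical neighbours whose reads cannot be assigned with certainty. Of 29 cell cycle genes, 1 rose and 15 fell in females (1 and 16 adjusted over the list). The set test gave adjusted p = 0.0010, and 0.69 with estimated correlation. The kinase gene aurB was at -0.45 and the replication origin gene Orc1 at 0.49.

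Many DNA damage and p53 response genes rose in Set2 mutants, but the list did not pass with estimated correlation. Of 21 genes of this list, 13 rose and 2 fell in males and 13 and 3 in females (13 and 2, and 13 and 3, adjusted over the list). Their adjusted p was 0.0060 in males and 0.0045 in females, and 0.17 and 0.30 with estimated correlation. The repair gene PolZ1 stood at 40.4 ± 2.82 CPM against 20.7 ± 0.632, log2 fold change 0.97, adjusted p = 6.6e-15 in males, and at a log2 fold change of 0.53 in females. Ku80 (0.75 and 0.54) rose in both sexes, Gadd45 in males (1.63), and the apoptosis gene hid (0.97) and the cytokine gene upd3 (2.68) in females. Of 11 ring gland genes, markers of another tissue, 8 rose and 0 fell in males (9 and 0 adjusted over the list). As a list they had adjusted p = 0.0057, and 0.56 with estimated correlation. The ecdysone synthesis gene sro was at 2.39. Sxl fell in males (log2 fold change -0.41, adjusted p = 0.0012). In the full fit neither roX1 nor roX2 was called in any mutant, and msl-2 was called in H3.2K36R females alone. The roX2 levels of Set21 and yw males did not overlap (43.9 ± 4.88 CPM against 71.2 ± 2.82). When only the compared libraries are fitted, roX2 (log2 fold change -0.70, adjusted p = 6.6e-04) and roX1 (-0.22, adjusted p = 0.036) are called in Set2 males and roX2 (-0.62, adjusted p = 0.0090) in H3.2K36R males. Without H3.3WTH3.2K36R female library 1, roX1 (adjusted p = 0.0094) and roX2 (adjusted p = 0.039) are called in H3.2K36R females.

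A further 10 lists passed in no comparison, with these counts in Set2 males. 2 of 20 antimicrobial and immune genes rose and 0 fell (2 and 0 adjusted over the list, adjusted p = 0.35), and 1 of 12 cuticle and trachea genes rose and 0 fell (1 and 0 adjusted over the list, adjusted p = 0.76). 27 of 86 detoxification genes rose and 18 fell (28 and 18 adjusted over the list, adjusted p = 0.58), and 5 of 25 ecdysone response genes rose and 4 fell (5 and 4 adjusted over the list, adjusted p = 0.77). 2 of 16 fat body genes rose and 2 fell (1 and 1 adjusted over the list, adjusted p = 0.87), and 5 of 19 glia genes rose and 7 fell (5 and 7 adjusted over the list, adjusted p = 0.59). 2 of 16 muscle genes rose and 4 fell (2 and 4 adjusted over the list, adjusted p = 0.31), and 17 of 78 odorant binding and gustatory genes rose and 9 fell (17 and 8 adjusted over the list, adjusted p = 0.13). 2 of 13 sex determination genes rose and 5 fell (2 and 5 adjusted over the list, adjusted p = 0.24), and 4 of 17 testis and sperm genes rose and 2 fell (4 and 2 adjusted over the list, adjusted p = 0.42).

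In Set2 males 5458 genes passed, 2784 higher and 2674 lower, 1167 of them at least 2-fold, and in females 5155, 2543 higher and 2612 lower, 1178 of them at least 2-fold. In males X-linked genes were over-represented among the lower genes (odds ratio 3.06, Fisher's exact test across genes, p = 4.7e-97) and under-represented among the higher ones (odds ratio 0.490, p = 3.1e-28). In females the odds ratios were 1.11 (Fisher's exact p = 0.073) and 0.686 (p = 2.8e-09).

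**Figure D3:**
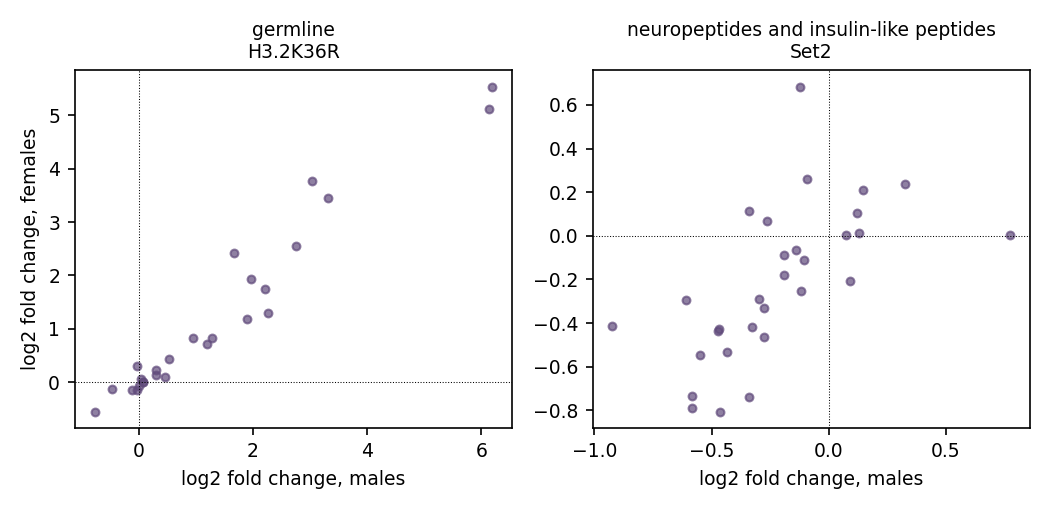
Log2 fold changes in males (x axis) and females (y axis) of the 26 germline genes in the H3.2K36R mutant and the 30 neuropeptide and insulin-like peptide genes in the Set2 mutant, 1 point per gene. In males 17 germline genes rose and 13 neuropeptide genes fell.

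X-linked expression relative to autosomal expression was lower in Set21 males than in yw males. The median of X-linked genes against autosomal genes, per library and centred on the 6 libraries compared, stood at -0.081 ± 0.018 in Set21 males and 0.083 ± 0.0066 in yw males (log2, n = 3). The difference of -0.16 (SE 0.011) equals a change of -10.7%, and all 3 mutant libraries lay below all 3 controls (exact permutation test, 2-sided, p = 0.10, the smallest that 3 against 3 libraries allow). In Set21 females the difference was -0.027 (SE 0.0058, exact p = 0.10). For H3.2K36R it was -0.017 (exact p = 0.20) in males and 0.0098 (exact p = 0.40) in females, and for H3.3K36R -0.018 and -0.013 (exact p = 0.10 each). Without the expression filter the shift is -0.105 in Set2 males and -0.0116 in Set2 females, and -0.00169 and -0.00331 in H3.3K36R. Across genes, 277 of 2016 X-linked genes rose and 820 fell in Set2 males (285 and 838 adjusted over the list), with adjusted p = 1.1e-06, and 3.4e-04 with estimated correlation. The median log2 fold change of these genes was -0.12 and 67.8% of them lay below the autosomal median, while their mean was 0.077, of the opposite sign. Arms 2L, 2R, 3L and 3R did not pass in Set2 males.

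**Figure D4:**
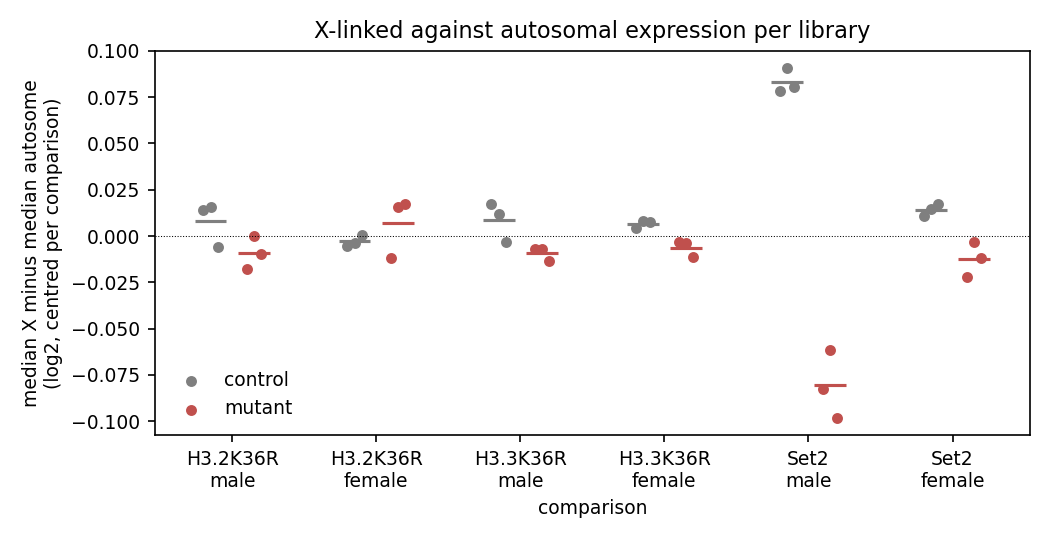
Median X-linked minus median autosomal expression (log2, centred per comparison) in each library of the 6 mutant and control pairs, 3 mutant and 3 control points each, with lines at the means. The 3 Set21 male libraries average -0.081 and the 3 yw male libraries 0.083.

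The difference between the male and the female value was -0.14 for Set2 (SE 0.013), -0.027 for H3.2K36R (SE 0.013, exact permutation p = 0.06) and -0.0050 for H3.3K36R (SE 0.0071, exact p = 0.70). In males the Set2 value lay below that of H3.2K36R by -0.15 (SE 0.014) and that of H3.3K36R by -0.15 (SE 0.013). For these 3 Set2 differences the large male shift sets the exact p (0.10, 0.095 and 0.10), which does not test the difference. With sex labels permuted within genotype, exact p was 0.56 for H3.2K36R and 0.92 for H3.3K36R. That of Set2 (0.10) is likewise set by the large Set21 sex difference. In females the differences were -0.036 (SE 0.011, exact p = 0.02) and -0.014 (SE 0.0065, exact p = 0.37). H3.2K36R and H3.3K36R differed by 0.0011 in males (SE 0.011, exact p = 0.96) and 0.023 in females (SE 0.010, exact p = 0.06). Over the family of 9, adjusted p was 0.15 or above. With the mean in place of the median, the H3.2K36R shift is 0.118 in males, of the opposite sign, and 0.0994 in females. Set2 minus H3.2K36R is then -0.262 in males and -0.148 in females, and H3.2K36R minus H3.3K36R 0.130 in females, with exact p = 0.005 each. The H3.2K36R difference between the sexes is -0.036 without mutant female library 1 (exact p = 0.01) and -0.035 without control male library 3 (exact p = 0.035). The female difference between the histone mutants is 0.032 without H3.3WTH3.2K36R female library 1 (exact p = 0.005), and the male H3.3K36R value is -0.0099 without control male library 1.

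Chromosome 4 moved in Set2 females. Measured in the same way, it stood at -0.13 ± 0.011 in Set21 females and 0.12 ± 0.047 in yw females, a difference of -0.25 (exact permutation p = 0.10, all 3 mutant libraries below all 3 controls). In Set21 males the difference was -0.010 (exact p = 0.70), and the male minus female difference was 0.24 (exact p = 0.07, and 0.06 with sex labels permuted). Of 105 genes 13 rose and 64 fell (15 and 71 adjusted over the list) in females (adjusted p = 3.5e-07, and 0.45 with estimated correlation), against 29 rose and 21 fell (29 and 21 adjusted over the list) in males (adjusted p = 0.59, and 0.92 with estimated correlation). In H3.2K36R males the difference was -0.069 (exact p = 0.10), in H3.2K36R females 0.0080 (exact p = 0.70), and in H3.3K36R -0.014 in males (exact p = 0.70) and 0.018 in females (exact p = 0.80). The Y chromosome rose in Set2 males (23 of 29 rose and 2 fell (24 and 2 adjusted over the list), adjusted p = 1.1e-06, and 0.31 with estimated correlation), against yw males almost without Y-linked RNA.

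**Figure D5:**
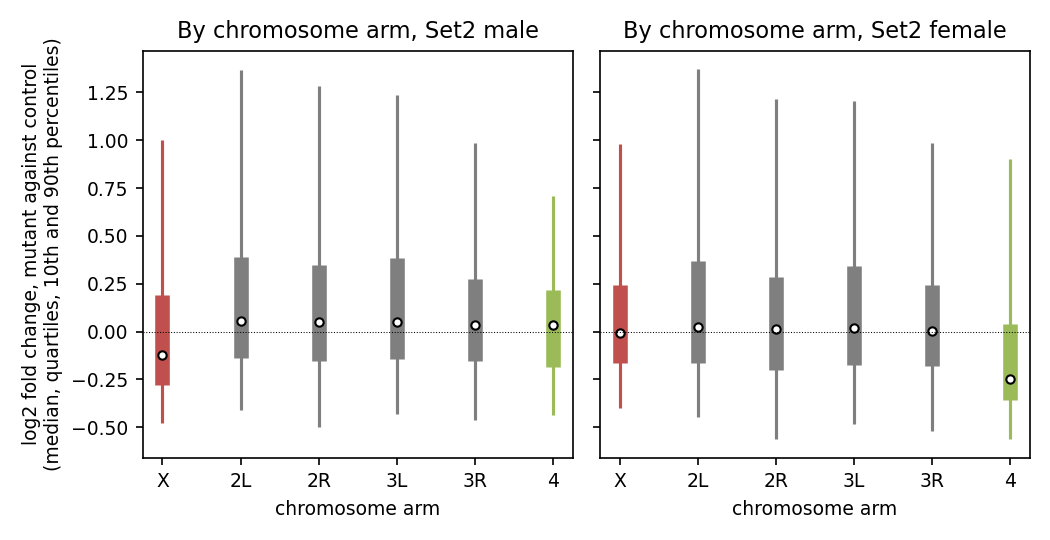
Distribution of log2 fold changes by chromosome arm in Set2 mutant males and females (points are medians, boxes quartiles, lines the 10th and 90th percentiles). The X median is -0.12 in males, and chromosome 4 lies lower in females than in males.

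The Set2 response, Set21 against yw, differed between the sexes, mostly on the X and chromosome 4. Of the 417 genes with a different response, 107 had a higher and 310 a lower response in males, and 290 of the lower ones were X-linked. Of 2016 X-linked responses, 18 were higher and 290 were lower in males (43 and 451 adjusted over the list). Camera gave them adjusted p = 8.6e-19, and 7.7e-08 with estimated correlation. Of 105 chromosome 4 responses, 37 were higher and 2 were lower in males (47 and 2 adjusted over the list). Tested together, they had adjusted p = 3.1e-25, and 0.019 with estimated correlation. On chromosome 4 the calcium pump gene PMCA (difference of log2 fold changes 0.50, adjusted p = 5.3e-08) and Gyf (0.38, adjusted p = 5.3e-08) had higher responses in males. PMCA stood at 1028 ± 33.8 CPM in Set21 males and 936 ± 38.9 in yw males, and at 704 ± 14.8 and 907 ± 14.8 in females. On the X, snf, a splicing factor gene, had a lower response (-0.42, adjusted p = 1.2e-06) and gd a higher one (1.82, adjusted p = 5.3e-08). The response of sle was higher (0.32, adjusted p = 1.2e-06), and Set2 itself fell further in males (-0.25, adjusted p = 0.0014).

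Of 29 Y-linked Set2 responses, 0 were higher or lower in males (0 adjusted over the list). For this list adjusted p was 2.0e-18, and 0.019 with estimated correlation. Of 29 cell cycle responses, 0 were higher or lower in males (0 adjusted over the list). Against all other genes, adjusted p was 0.040, and 0.97 with estimated correlation. Of 32 proteasome responses, 0 were higher and 4 were lower in males (0 and 4 adjusted over the list). This set had adjusted p = 0.0057, and 0.97 with estimated correlation. The first 2 lists passed upward and the proteasome downward.

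For H3.3K36R 22 genes responded differently between the sexes, 16 higher and 6 lower in males, all X-linked. They include Mgstl (-0.53, adjusted p = 6.7e-05), Pa1 (0.39, adjusted p = 7.9e-04), kat80 (-0.33, adjusted p = 7.9e-04) and Rubicon (0.47). When only the compared libraries are fitted, the calls of kat80 (adjusted p = 0.053) and Rubicon (adjusted p = 0.24) are lost. That of Rubicon is also lost without control female library 2 (adjusted p = 0.067), control male library 1 (adjusted p = 0.058), mutant female library 3 (adjusted p = 0.061) or mutant male library 1 (adjusted p = 0.050). The count is 9 without mutant male library 1 and 11 without mutant female library 3, mutant male library 2 or mutant male library 3. It is 12 without control female library 1 or control male library 1, and 13 without control female library 2. DESeq2 gave 43 genes, and edgeR 9 when only the compared libraries were fitted.

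These lists had lower H3.3K36R responses in males. Of 12 eye disc responses, 0 were higher or lower (0 adjusted over the list). Camera on this list gave adjusted p = 1.6e-04, and 0.52 with estimated correlation. Of 32 proteasome responses, 0 were higher or lower (0 adjusted over the list). Taken as a set, they had adjusted p = 1.2e-08, and 0.77 with estimated correlation. Of 10 salivary gland responses, 0 were higher or lower (0 adjusted over the list). Relative to other genes they had adjusted p = 4.6e-04, and 0.77 with estimated correlation. The next had higher ones. Of 72 mitochondrial ribosomal protein responses, 0 were higher and 0 were lower (1 and 0 adjusted over the list). With the preset correlation adjusted p was 4.6e-04, and 0.77 with estimated correlation. Of 30 neuropeptide responses, 0 were higher or lower (0 adjusted over the list). Jointly they had adjusted p = 4.7e-04, and 0.77 with estimated correlation. Of 11 ring gland responses, 0 were higher or lower (0 adjusted over the list). The set test gave adjusted p = 0.013, and 0.77 with estimated correlation. By edgeR 552 of 12167 genes had an unadjusted p under 0.05, fewer than chance gives, and 22 passed.

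For H3.2K36R 8 genes responded differently between the sexes by edgeR, 2 higher and 6 lower in males, against 37 by DESeq2 and 734 by edgeR at an unadjusted p under 0.05. With libraries paired across the sexes by their number the count was 5, with 2 of the 8 kept and 6 lost. Arc1, a capsid-like gene of synapses (0.91, adjusted p = 0.027), had a higher response. The lipoprotein gene apolpp on chromosome 4 (-0.57, adjusted p = 0.027), SP1173 (-0.40) and Idgf3 (-0.36) had lower ones. The calls of all of these are lost in each setting that gives a count of 0 by edgeR. The replicate block also ends those of apolpp (adjusted p = 0.089), Idgf3 (0.089) and SP1173 (0.18). Without control female library 2, Idgf3 (0.091) and SP1173 (0.14) lose theirs, and SP1173 also without control male library 1 (0.054) or 3 (0.069). The count is 0 by edgeR without control female library 1 or 3, control male library 2, mutant female library 2 or 3, or mutant male library 2 or 3. It is also 0 with the roX2 level of female libraries as a covariate and when only the compared libraries are fitted. It is 1 with the replicate block, 2 without control female library 2, 4 without control male library 1 and 21 without mutant female library 1.

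These lists had lower H3.2K36R responses in males. Of 105 chromosome 4 responses, 0 were higher and 2 were lower (0 and 3 adjusted over the list). Their adjusted p was 1.7e-09, and 0.65 with estimated correlation. Of 25 differentiated neuron responses, 0 were higher or lower (0 adjusted over the list). As a list they had adjusted p = 0.027, and 0.71 with estimated correlation. Of 10 salivary gland responses, 0 were higher or lower (0 adjusted over the list). Camera gave them adjusted p = 0.0067, and 0.71 with estimated correlation. The next had higher ones. Of 29 Y-linked responses, 0 were higher or lower (0 adjusted over the list). Tested together, they had adjusted p = 2.4e-20, and 0.066 with estimated correlation. Of 72 mitochondrial ribosomal protein responses, 0 were higher or lower (0 adjusted over the list). For this list adjusted p was 1.3e-06, and 0.71 with estimated correlation. Of 26 germline responses, 0 were higher and 0 were lower (3 and 0 adjusted over the list). Against all other genes, adjusted p was 0.010, and 0.16 with estimated correlation. Of 11 ring gland responses, 0 were higher or lower (0 adjusted over the list). This set had adjusted p = 0.0067, and 0.71 with estimated correlation. Of 29 cell cycle responses, 0 were higher or lower (0 adjusted over the list). Camera on this list gave adjusted p = 0.027, and 0.89 with estimated correlation. Of 73 oxidative phosphorylation responses, 0 were higher or lower (0 adjusted over the list). Taken as a set, they had adjusted p = 0.048, and 0.89 with estimated correlation. These lists passed with few or none of their members called.

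Genes called in both sexes of a mutant mostly moved the same way. For H3.2K36R, of 4074 genes called in either sex, 951 were higher and 1082 lower in both (166 and 219 if the lists were independent), and 2 moved in opposite directions. For H3.3K36R, of 1443, 295 were higher and 244 lower in both (24.7 and 14.4 if independent), with 2 opposite, and for Set2, of 6679, 1956 and 1935 (582 and 574 if independent), with 43 opposite. The log2 fold changes of males and females correlated across genes, which are not independent replicates, with Pearson's r of 0.812, 0.462 and 0.740 and Spearman's rho of 0.659, 0.433 and 0.730.

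The mutants shared called genes in the same direction more often than independent lists would. In males Set2 and H3.2K36R shared 711 higher and 767 lower genes (342 and 351 if independent), and in females 593 and 743 (282 and 358). Set2 and H3.3K36R shared 308 and 237 in males (164 and 109) and 229 and 171 in females (87.6 and 75.8). H3.2K36R and H3.3K36R shared 185 and 117 in males (87.9 and 65.1) and 153 and 79 in females (46.5 and 48.4). In opposite directions, males and females of these pairs shared 339 and 335 (694 and 638 if independent), 209 and 94 (271 and 164), and 152 and 86 (155 and 96.6). Log2 fold changes correlated weakly across genes for the histone mutants in males (Pearson's r 0.0769, Spearman's rho 0.0625), and most strongly for Set2 and H3.2K36R males by r (0.335, rho 0.272). In all 3 mutants 124 genes were higher and 83 lower in males (20.1 and 14.3 if independent), and 102 and 55 in females (9.72 and 10.4). Marf1 was higher in all 3 in both sexes. In males c(3)G, a gene of the synaptonemal complex (log2 fold changes 0.86, 0.45 and 0.43 for H3.2K36R, H3.3K36R and Set2), l(2)41Ab (0.49, 0.55 and 1.25) and the potassium channel gene eag (0.35, 0.57 and 0.51) followed. In females the others were Rcd-1r (4.69, 1.43 and 2.39), Dhc98D (4.51, 1.21 and 1.58) and Nt5b (0.72, 0.28 and 0.34), whose H3.3K36R call is lost when only the compared libraries are fitted (adjusted p = 0.056). When only the compared libraries are fitted, Set2 and H3.2K36R share 937 genes in males, Set2 and H3.3K36R 164 in females, and both histone mutants 86 in females.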

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

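Chosen only after the result was seen were the tests of expression level, strain variants and Y-linked RNA, the splits of mutant and control libraries, the count of splits that swap equally, and the measure of chromosome 4; the tests of the roX2 level (the code's added demand on the 2 farthest libraries was dropped after the values were seen) and the splits of interactions and of control sexes were written down first. The response differed between the sexes for 8 genes in H3.2K36R, 22 in H3.3K36R and 417 in Set2, by the interaction test, and these stand here because an effect in males differs from that in females. In Set2, 290 X-linked genes had a lower and 37 chromosome 4 genes a higher response in males than in females. The X-to-autosome shift of Set2 minus that of H3.2K36R in females was -0.0364 (exact p = 0.02, adjusted p = 0.15 over 9 comparisons).

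Other splits of the same libraries tested these counts. For control sexes 1 of 100 splits, the real one, gave 990 genes, the highest other gave 32, and chance can be excluded. For the interactions 22 of 100 splits gave at least the 8 genes of H3.2K36R (highest other 652), 13 the 22 of H3.3K36R (highest other 955) and 13 the 417 of Set2 (highest other 1463), so all 100 together do not exclude chance. Splits calling many times the real count point to a structure of the samples. Those that swap unequal numbers of males and females between the genotypes bring the sex difference into the contrast. Among the 38 splits that swap as many in each genotype, 6 reached the H3.2K36R count, the real one included (highest other 107). For H3.3K36R and Set2 only the real one did (highest others 1 and 2). The others mix the sexes within groups, adding spread, and cannot exclude chance. For mutant against control, 3 libraries against 3 give 10 splits, too few for a share under 0.05. In each, 1 split, the real one, was as large. The real counts and highest others were 3091 and 1 for H3.2K36R males, 3018 and 1 for females, 1212 and 0 for H3.3K36R males, 772 and 262 for females, 5458 and 0 for Set2 males, and 5155 and 1 for females, by edgeR.

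In 9 of 18 female libraries roX2 exceeded 5% of the level in males of the same genotype. Carry-over of reads stays open. Genes absent from a genotype but abundant elsewhere (1 to 5 per library) reached at most 1.11% of their level elsewhere in those libraries. There roX2 stood at 14.4% or more of the level elsewhere. Such genes cannot show carry-over from males of the same genotype. Male tissue in the female samples may be the source: across the 18 female libraries, centred within group, roX2 correlated with the slope of 980 other sex-different genes on their male minus female difference (Pearson's r = 0.661, permutation p = 0.0495; Spearman's rho = 0.664, permutation p = 0.0218). Without the 2 libraries farthest from the median, r was 0.512 (permutation p = 0.22) and rho 0.609 (permutation p = 0.11), so with 16 libraries the relation no longer passes, while the share of Y-linked RNA correlated with roX2 as well (r = 0.656, permutation p = 0.0103; without yw, chosen after seeing the values, r = 0.732, permutation p = 7.0e-04; without the 2 libraries r = 0.663, permutation p = 0.10). A roX2 level that differs between females for biological reasons was not tested.

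X-linked expression was lower in Set2 mutant males. Expression level as the cause is argued against, since against autosomal genes of matched expression the median was -0.160 (95% bootstrap interval -0.173 to -0.147). X-linked variants acting in both sexes are argued against by the female shift of -0.0266, and low Y-linked RNA in yw males by the male minus female X difference of -0.0461 in yw, which lies at the upper end of the histone genotypes (-0.0665 to -0.0458), while that of Set21 was -0.181. As a hypothesis, lost Set2 may lower X-linked expression in males. Strain differences acting in 1 sex stay open, as no second allele to separate them is in these data.

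Chromosome 4 expression was lower in Set2 mutant females, with an exact p of 0.07 for the difference between the sexes. Against autosomal genes of matched expression the median was -0.191 (95% bootstrap interval -0.240 to -0.132), which argues against expression level as the cause. Chromosome 4 variants acting in both sexes are argued against by the male shift of -0.0104, and low Y-linked RNA in yw males by the male minus female difference of 0.0171 in yw, inside the range of the histone genotypes (-0.0625 to 0.0511), with 0.216 in Set21. As a hypothesis, Set2 may act on chromosome 4 in a way that differs between the sexes. Strain differences acting in 1 sex stay open here too.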

How the results depend on the processing

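The roX2 covariate, the replicate block across sexes, permuted sex labels, halved counts and the reduction of both H3.2 genotypes to libraries 2 and 3 were chosen after seeing the data. Leaving out 1 library left 211 values within 1.5 times a count, or within the spread and the side of the threshold, moved 20 and carried 3 past the threshold. The other settings left 199 so, moved 37, carried 6 past the threshold and took 2 below it. No called value changed sign, and uncalled shifts that changed sign count among the moved or unmoved ones. Except where a cause is given, the cause was not tested. RLE size factors, TMM factors from autosomal genes and halved counts changed no count of genes called in a comparison by over 1.5 times. The last 2 were not run for lists. TMM factors from autosomal genes moved the share of higher calls in Set2 males from 51.0% to 44.4%.

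Requiring at least a 2-fold change left, by construction, 728 and 620 genes in H3.2K36R males and females, 264 and 228 in H3.3K36R, 1167 and 1178 in Set2, 1, 4 and 24 in the H3.2K36R, H3.3K36R and Set2 interactions, and 91 between control sexes. With only the compared libraries, fewer libraries estimate the spread. H3.3K36R females then had 320 genes, the H3.3K36R interaction 9 and the H3.2K36R interaction 0 by edgeR. Overlaps fell to 937 genes for Set2 and H3.2K36R males, 164 for Set2 and H3.3K36R females and 86 for both histone mutants in females. DESeq2 called 37 genes in the H3.2K36R interaction and 43 in that of H3.3K36R. With the roX2 level of female libraries as a covariate, the H3.2K36R interaction had 0 by edgeR.

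With the replicate block, the H3.2K36R interaction had 1 gene and that of H3.3K36R 14. The counts were 2919 and 2881 in H3.2K36R males and females, 1115 and 734 in H3.3K36R, 5370 and 5049 in Set2, 370 in the Set2 interaction and 1016 between control sexes. The paired test left the Set2 minus H3.2K36R shift in females at -0.0364 by construction, with exact p = 0.0625 in place of 0.02. With the replicate block across sexes, the interactions of H3.2K36R and H3.3K36R had 5 and 13 genes. The block kept 82 list calls and added 10. In H3.2K36R males same-numbered mutants and controls correlated at 0.188, -0.0727 and 0.166, so pairing there stays open. Elsewhere these correlations ran from -0.0240 to 0.0157 and -0.0389 to 0.147 in H3.3K36R males and females. In Set2 they ran from -0.0724 to 0.0220 and -0.0868 to -0.00633. Those of males and females ran from -0.148 to -0.0994 in H3.3CtrlH3.2HWT, 0.0270 to 0.0547 in H3.3K36RH3.2HWT, -0.0185 to 0.107 in yw and -0.0896 to 0.0398 in Set21.

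With the mean in place of the median, the X shifts were 0.118 and 0.0994 for H3.2K36R males and females, -0.00456 and -0.0302 for H3.3K36R, and -0.144 and -0.0487 for Set2. The differences were then -0.262 for Set2 minus H3.2K36R males (exact p = 0.005), and 0.122 and 0.130 for H3.2K36R minus H3.3K36R males and females (exact p = 0.035 and 0.005). The strict filter gave -0.0349 for H3.2K36R males, -0.00937 for H3.3K36R females, -0.180 for Set2 males and -0.0313 for Set2 minus H3.2K36R females (exact p = 0.07). No filter gave -0.00169 and -0.00331 for H3.3K36R males and females, -0.105 and -0.0116 for Set2, and -0.0111 for the H3.2K36R sex difference (exact p = 0.045). A prior count of 0.5 gave 0.0236 (exact p = 0.03) and libraries 2 and 3 alone gave 0.0307 (exact p = 0.0167) for H3.2K36R minus H3.3K36R females. With an estimated correlation 11 lists passed, 8 of the 82 and 3 others, and fry kept 48, RLE size factors 78 and the strict filter 56.

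Without 1 library, counts ranged from 2457 to 2790 and 2104 to 2647 in H3.2K36R males and females, 746 to 990 and 571 to 712 in H3.3K36R, 4752 to 5230 and 4406 to 4521 in Set2, 294 to 391 in the Set2 interaction and 860 to 1055 between control sexes. The H3.2K36R interaction ranged from 0 by edgeR (37 by DESeq2 in the full fit) to 21 (without mutant female library 1). That of H3.3K36R ranged from 9 (without mutant male library 1) to 27 (without control female library 3). The H3.3K36R male shift ranged from -0.0220 to -0.00990, the latter without control male library 1. The H3.2K36R sex difference ranged from -0.0360 (without mutant female library 1) to -0.0210, and the female H3.2K36R minus H3.3K36R difference from 0.0177 to 0.0321 (without H3.3WTH3.2K36R female library 1).

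Of 367 values of named genes, 296 were called. DESeq2 added 3, only the compared libraries lost 25 and added 10, and the replicate block lost 11 and added 3. Leaving out 1 library lost 36 and added 6 in at least 1 case. Depth limits genes near the floor, such as most Y-linked genes, whose lists rest on few reads.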

Other observations

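All 22 genes whose H3.3K36R response differed between the sexes by edgeR lay on the X, where 2016 of 12167 tested genes lie. Fisher's exact test across genes gave p = 3.9e-13 for the 16 higher and 2.3e-05 for the 6 lower in males. X variants differing between these H3.3 genotypes were not tested. The eye pigment gene w was close to absent in yw (0.110 ± 0.0247 CPM in males and 0.111 ± 0.0468 in females) and in Set21 (0.414 ± 0.124 and 0.656 ± 0.0725), against 180 to 274 CPM in the 8 groups of histone genotypes. The Y-linked sperm gene kl-2 reached 2.62 ± 0.840 CPM in H3.3WTH3.2K36R males and 1.40 ± 0.501 in Set21 males, and at most 0.335 in any other group (n = 3 each).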
